A study of Oryza sativa with 2 samples.

How the data were processed

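Leaf RNA of 2 rice lines that overexpress OsHAP2E and of Nipponbare wild type was compared on 2 Agilent rice arrays, 1 per line (line 4 is replicate 1 and line 18 replicate 2). Per the labels, seedlings grew in soil at 23 to 26 °C with 16 h of light and 8 h of dark, leaves were taken at the 4-leaf stage, and 10 µg of total RNA were copied from an oligo-dT primer with Cy3 for wild type and Cy5 for the transgenic line. The labels give no dye swap. They do not say how many plants or RNA extractions lie behind each sample; p-values then measure only the spread between these samples. Both arrays lay on 1 slide, so no slide separates the lines. A difference in RNA extraction or labelling between them is not excluded.

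The deposited array files hold, for each of 45151 spots, the mean intensity of the pixels in each channel and the median intensity of the local background, which the authors read from the scanned image with Agilent Feature Extraction 10.5.1.1. Per the file headers, the processed intensity of each channel was background subtracted, detrended and dye-normalised by that program, and the ratio is given as the log10 of Cy5 over Cy3. Per the file headers, the p-value of each log10 ratio comes from the error model of Feature Extraction for 1 array. The deposited series file holds the log10 ratio of both arrays. Its 43734 line 18 values equal the array files by feature number within a tolerance of 1e-06, while in 5162 of them (11.8%) the accession text and the line 4 value belong to another feature number. It was used only as an alternative, joined by accession for line 4.

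The main analysis started from mean intensities and background medians. In R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), each channel was corrected by normexp with an offset of 50. Each array was normalised by loess, with 1417 control spots given no weight. The 510 spots of genome, random and other control probes not marked as controls were left out. Spots of 1 probe were averaged, which gave 42419 probes of 29714 genes. A probe was kept if it was well above background on both arrays in Cy5 or on both arrays in Cy3 and no channel was an outlier for uniformity. This left 32808 probes and 22469 genes (22452 with a rice locus name). Of these, 6465 had several kept probes, and the brightest stood for the gene. In 137 of them kept probes had opposite signs and differed by over 1 on the log2 scale. The filter left 1135 genes with wild type not well above background on either array, and 58 with the lines not well above background. Their ratios are given as bounds ("at least") where the dim signal lay under the lowest signal well above background in its channel, and as measured otherwise. A total of 920 genes share 188 probe sequences with another gene, so that their values are not separate measurements. No spot was saturated.

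The log2 ratio of each gene was tested against 0 by limma with an intercept only and eBayes (prior degrees of freedom 2.59), two-sided, with Benjamini-Hochberg adjusted p at 0.05. The labels name a single wild type control and do not say whether both arrays had the same RNA, so it was taken as 1 control. The ratio leaves out the control's own spread between samples, and any effect of the dye stays in it. Gene lists were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 5 measured genes, and limma p-values were also adjusted over the list alone. Percentiles of list medians come from 10000 random lists of the same size and similar signal. The gene lists, tests, thresholds and the rule for named genes were fixed before the data were examined. The lists match words in the gene descriptions: NF-Y subunits, pathogenesis-related proteins, chitinases and beta-1,3-glucanases, peroxidases, glutathione S-transferases, phenylpropanoid and terpene enzymes, WRKY, NAC and AP2/ERF factors, NBS-LRR proteins, receptor kinases, light harvesting, Calvin cycle and chlorophyll biosynthesis, ribosomal, heat shock and LEA proteins. Further lists hold hormone pathways, nutrient transport, carbohydrate metabolism, cell wall growth, antioxidants, senescence, and markers of dividing cells, seed, root, time of day and transposable elements.

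Genes were named by this rule: the 12 highest and 12 lowest by the smaller ratio of the 2 lines among described genes with the same sign in both; in each list that passed camera or concerns defence, photosynthesis, drought or the clock, up to 4 members by the same ranking; all NF-Y subunits; and the 4 described genes that differed most between the lines. Descriptions and locus names are those of the array files. None of the tested loci or transcripts (0 of 22469) was found in the reference gene table, which holds 2 genes with HAP2 among their names and 0 with HAP2E. Coordinates and the genome build are not given in the sources used here. A total of 8632 tested genes have no description and could enter no list.

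On simulated data with 200 changed genes per run (20 runs), limma called 0.125% of genes changed 2-fold, 4.13% at 4-fold, 66.1% at 8-fold and 92.0% at 32-fold, with 7.20 false calls per run. At an unadjusted p under 0.05, camera found a list of 50 genes shifted by 0.5 on the log2 scale in 100% of 100 runs. It found an unshifted list in 1%. Smaller shifts were not tried. These simulated data had independent genes and arrays and no shared control, so the rates need not hold for the real arrays. A simulation with a shared control error and no change (100 draws) gave the correlation, covariance, overlap and limma counts that 1 common control produces if both lines and the control have the same spread. The alternatives were no background subtraction, a normexp offset of 0, the processed signals of Feature Extraction, median centring in place of loess, scaling to the same median absolute deviation, no filter, signals above background in both channels, the mean of a gene's probes, the deposited table, and leaving out each line. Further ones were eBayes with trend or robust, treat at 1.5-fold, the Feature Extraction p-value, camera with estimated correlation, fry, random lists, a 1.5-fold threshold and bright genes alone. Added after the data were seen were lists without accidental members, 1 gene per probe sequence, and line 4 centred so that its spike-in spots read as in line 18.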

Results

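Transcript levels were measured in leaves of rice (cultivar Nipponbare) at the 4-leaf stage, in wild type plants and in 2 transgenic lines, named line 4 and line 18, that carry OsHAP2E behind a strong promoter of cauliflower mosaic virus. OsHAP2E is a HAP2 protein, the A subunit of NF-Y, a trimeric transcription factor that binds the CCAAT box. Each line was hybridised in Cy5 on 1 rice array against wild type RNA in Cy3. The overexpression group therefore holds 2 samples, and no array has the dyes exchanged. Of the 43734 spots per array that are no controls, 31704 (72.5%) in Cy3 and 36956 (84.5%) in Cy5 were well above background on the line 4 array. On the line 18 array these were 31479 (72.0%) and 33265 (76.1%). The median signal above background was 144 in Cy3 and 220 in Cy5 on the line 4 array, and 135 and 457 on the line 18 array. A total of 22469 genes passed the filter on dim signals. The number of arrays, 2, limits the precision of every value. Values given with an SD are the mean log2 ratio of line over wild type over the 2 lines (n = 2).

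The comparison of the overexpression lines with wild type asks which genes differ in leaves that carry more OsHAP2E. The genes with the highest ratios in both lines include several of the defence lists fixed beforehand. Among the 12 highest were the peroxidase POC1 (Os07g0677500, 38.5-fold, 5.27 ± 2.51) and a chitinase, an enzyme that breaks down fungal cell walls (Os10g0542900, 23.3-fold, 4.54 ± 1.60). They also held a metallothionein, a small protein that binds metals (Os05g0202800, 17.5-fold, 4.13 ± 0.76), and the probenazole-inducible protein PBZ1 of the pathogenesis-related PR-10 family (Os12g0555500, 13.5-fold, 3.75 ± 1.36). Among the lowest ratios in both lines were those of a pair of cytochrome P450 genes (Os03g0658800, 25.8-fold lower, -4.69 ± 0.72, and Os06g0639800, 12.5-fold lower, -3.64 ± 0.23). They also held those of an acid phosphatase of class B (Os05g0190500, 16.2-fold lower, -4.02 ± 0.18) and a fasciclin domain protein (Os02g0308800, 14.5-fold lower, -3.86 ± 0.58). None of the 22469 genes passed limma at an adjusted p of 0.05, and the lowest adjusted p was 0.221. None passed with an intensity trend, a robust fit or treat either, while 3126 had a Feature Extraction p under 0.01 on both arrays with the same sign and 8 passed limma with line 4 centred on the spike-in spots. At an unadjusted p under 0.05, 3238 genes passed, 1882 with a positive and 1356 with a negative ratio. With no change, 1123 are expected if the arrays have independent errors, and 4826 (4529 to 5159 over 100 draws) in a simulation in which both share the error of 1 control. The count of 3238 does not exceed what that simulation gives. At an adjusted p under 0.05 the simulation gave 697 genes (145 to 1566), against 0 observed. It gave 26.8 genes at least 2-fold in opposite directions, against 7 observed. It gave both lines and the control the same spread, while the log2 ratios had an SD of 0.84 in line 4 and 0.46 in line 18. Its counts are therefore only a rough guide to these arrays.

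The other genes among the 12 with the highest ratios were a beta-1,3-glucanase (Os01g0940700, 3.71 ± 0.68), a barwin protein (Os11g0592000, 3.70 ± 1.11) and a thaumatin of the pathogenesis-related PR-5 type (Os03g0663500, 3.46 ± 0.78). They were followed by a basic secretory protein (Os10g0491000, 3.16 ± 0.29), RIR1a (Os10g0569400, 3.15 ± 0.66), the FtsH protease VAR2, a protease of the thylakoid membrane (Os06g0229000, 2.85 ± 0.07), and a pair of disease resistance response proteins. Wild type was not well above background for that pair, which were at least 8.33-fold (Os11g0215100) and, as measured, 7.96-fold (Os11g0214400) above it. Among the 12 lowest were the 10 kDa polypeptide of photosystem II (Os07g0147500, -3.51 ± 1.12), a further pair of disease resistance response proteins (Os11g0645400, -3.28 ± 0.68, and Os07g0636600, -2.95 ± 0.28) and a GDSL lipase (Os01g0216000, -3.19 ± 0.77). The others were a harpin-induced protein (Os02g0538700, -3.09 ± 0.32), cycloartenol synthase, an enzyme of sterol synthesis (Os11g0189600, -2.85 ± 0.26), a chalcone synthase family protein (Os03g0382100, -2.69 ± 0.18) and a terpene synthase (Os11g0286800, -2.51 ± 0.08). The adjusted p of these 24 genes lay between 0.221 and 0.254.

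**Figure D1:**
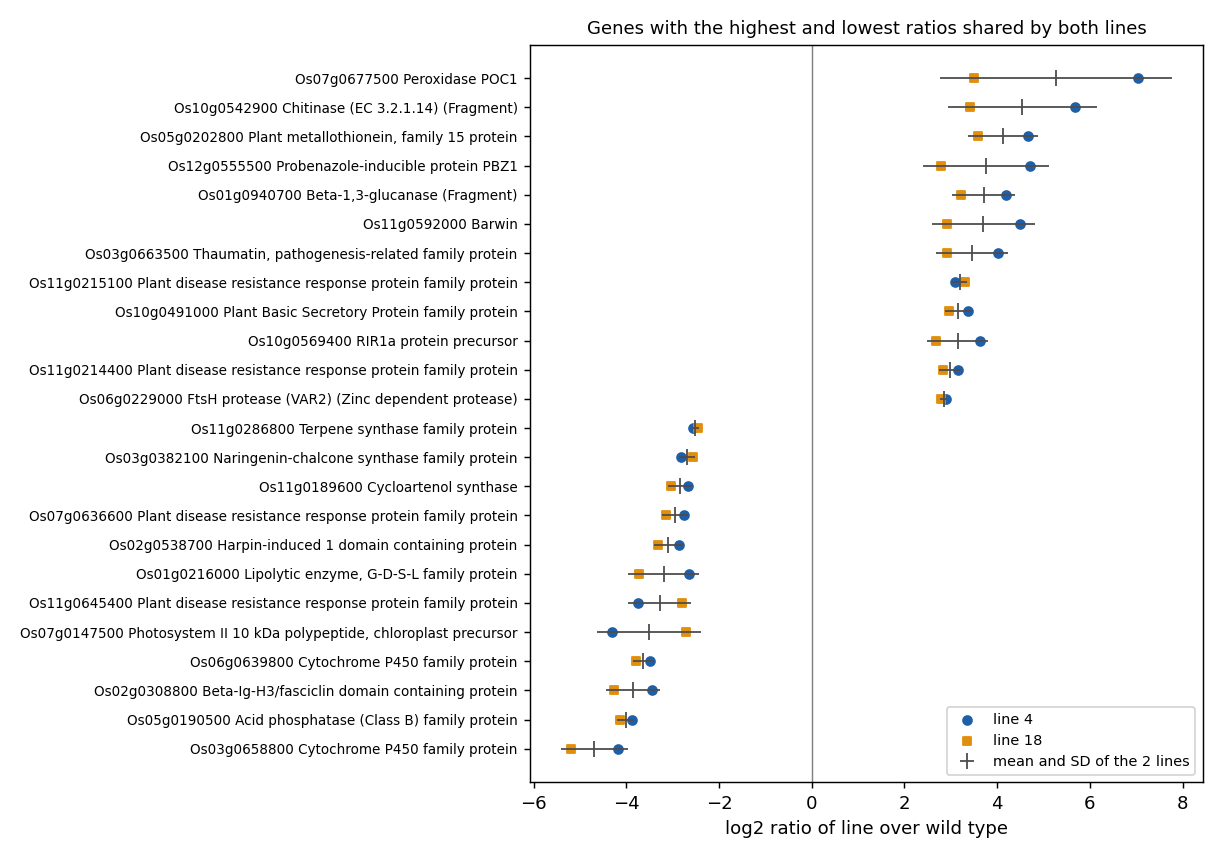
Log2 ratios of line over wild type (horizontal axis) for the 12 highest and the 12 lowest genes by the smaller ratio of the 2 lines, 1 gene per line of the plot. Circles are line 4, squares line 18, and bars the mean and SD of the 2 lines. The means of the 2 lines run from 5.27 for the peroxidase POC1 to -4.69 for the cytochrome P450 Os03g0658800, and none of the 24 genes passed limma.

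At least 2-fold ratios of the same sign in both lines were found for 613 genes, 390 of them higher and 223 lower than wild type, and of opposite signs for 7 genes. Line 4 alone had 3449 such genes (2496 higher and 953 lower) and line 18 alone 980 (656 higher and 324 lower). Lists of these sizes drawn independently would share 72.9 higher and 13.7 lower genes. A simulation in which both arrays share the error of 1 control and no gene changes gave 312 genes of the same sign on average, with 275 to 354 over 100 draws. The settings changed the total, which was 395 with line 4 centred on the spike-in spots (78 higher and 317 lower). It was 1110 with a normexp offset of 0, 1479 in the deposited table and 1534 with the processed signals of Feature Extraction. On the line 4 array, genes read by a probe sequence that 10 or more loci share had a median log2 ratio of 2.26, and 84.6% of these 409 genes were at least 2-fold above wild type, against 8.80% of 21536 genes read by a sequence of 1 locus. In line 18 the median of the 409 genes was 0.13 and 2.69% were at least 2-fold above wild type. These 409 genes are read by only 18 probe sequences, so their medians and shares count the same measurements many times.

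Of the 32 gene lists, 6 rose and 3 fell against the other genes of the arrays by camera at an adjusted p of 0.05. Those that rose hold chitinases and glucanases, WRKY factors, pathogenesis-related proteins, glutathione S-transferases, jasmonate genes and transposable elements. Those that fell hold ribosomal proteins, histones with cell cycle genes, and chlorophyll biosynthesis enzymes. None of the 9 calls held with an inter-gene correlation estimated from the 2 arrays, nor with fry, a rotation test of the genes of each list by themselves, for which the lowest adjusted p was 0.290. With the estimated correlation the lowest adjusted p by camera of any list was 0.731. The estimated correlation lay above the preset 0.01 for chlorophyll biosynthesis (0.71), jasmonate genes (0.33), ribosomal proteins (0.11) and pathogenesis-related proteins (0.08). It also did for transposable elements and histones (0.02 each). It lay below the preset for chitinases and glutathione S-transferases (-0.02 each) and WRKY factors (0.006), and their calls were lost too. With 2 arrays this setting thus cannot decide whether correlated genes account for the calls. These directions are relative to other genes: centring line 4 on the spike-in spots lowers all genes alike, to a median of -0.93, and tests no list. Ranges of list medians below are over 11 other settings without that one. The median moved by over 1.5 times in some setting for 30 of the 32 lists and changed sign for 6, none of them among the 9.

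The chitinases and beta-1,3-glucanases, enzymes that attack fungal cell walls, rose with a median log2 ratio of 0.85 (0.88 in line 4 and 0.38 in line 18, camera adjusted p = 6.2e-05), with a range of 0.19 (67 genes, no filter on dim probes) to 1.00. The list had adjusted p = 0.731 with an estimated correlation. Of 47 measured members, 28 were higher in both lines and 9 lower in both, with 14 at least 2-fold higher in both and 1 at least 2-fold lower. By limma, 20 of the members passed when adjusted over the list alone, against 0 over all genes. At an unadjusted p under 0.05 by limma, 21 of the 47 members passed, against 3238 of all 22469 genes. The simulation with a shared control and no change gave 4826 genes at that limit. Counts past limma adjusted over a list alone, here and below, therefore do not by themselves show changed members. After the 2 members already named, the next were glucanases, Os03g0600600 (6.90-fold, 2.79 ± 0.47) and Os01g0944900 (5.69-fold, 2.51 ± 0.63). The pathogenesis-related proteins rose with a median of 0.49 (0.74 in line 4 and 0.33 in line 18, camera adjusted p = 0.00118), with a range of 0.23 (56 genes, no filter) to 0.75 (Feature Extraction signals, and the same in the deposited table). This became adjusted p = 0.731 with an estimated correlation. Of 41 members, 25 were higher in both lines and 7 lower, 11 at least 2-fold higher in both, and 14 passed limma adjusted over the list alone. A pair of thaumatin-like genes had ratios of 3.24 ± 1.105 (Os12g0629700, 9.48-fold) and 2.94 ± 0.50 (Os12g0628600, 7.68-fold).

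**Figure D2:**
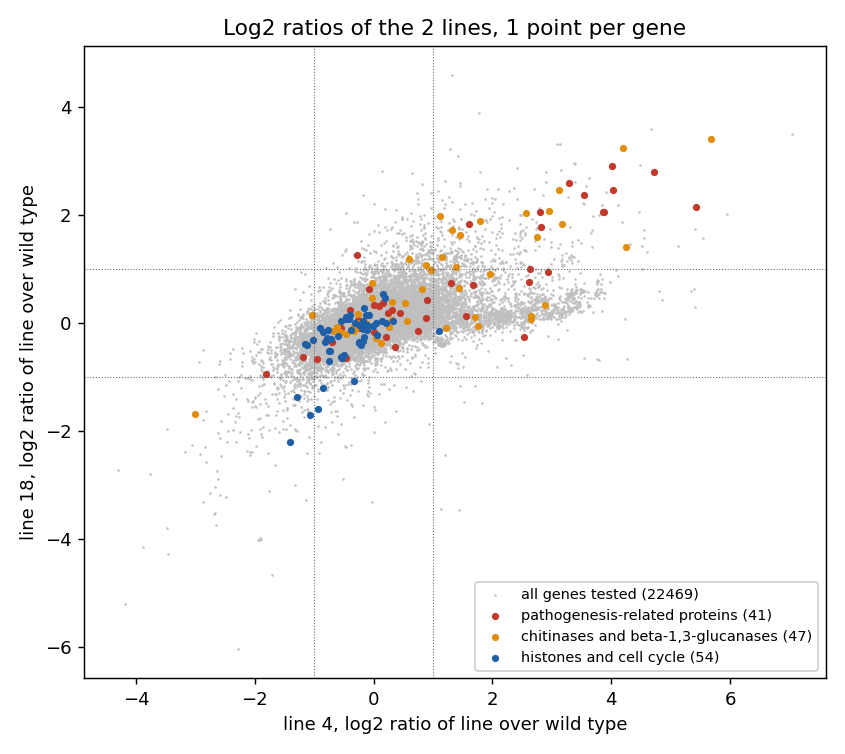
Log2 ratio of line over wild type in line 4 (horizontal axis) and in line 18 (vertical axis), 1 point per gene, with 3 gene lists in colour and dotted lines at a 2-fold ratio. Of the 41 pathogenesis-related genes 25, and of the 47 chitinase and glucanase genes 28, lie above 0 in both lines, while 36 of the 54 histone and cell cycle genes lie below 0 in both.

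The WRKY factors, transcription factors many of which act in defence, rose with a median of 0.40 (0.49 in line 4 and 0.29 in line 18, camera adjusted p = 7.7e-04), with a range of 0.23 (no filter) to 0.48. They had adjusted p = 0.731 with an estimated correlation. Of 59 members, 34 were higher in both lines and 8 lower, and 1 passed limma adjusted over the list alone. WRKY67 (Os01g0584900) was 4.70-fold above wild type (2.23 ± 0.33), WRKY19 (Os05g0571200) 3.82-fold (1.93 ± 0.84), WRKY72 (Os11g0490900) 3.72-fold (1.90 ± 1.29) and WRKY45 (Os05g0322900), a regulator of salicylic acid responses in rice, 3.12-fold (1.64 ± 0.76). The glutathione S-transferases, enzymes of detoxification, rose with a median of 0.25 (0.28 and 0.18, camera adjusted p = 0.00166), with a range of 0.16 (no filter) to 0.38 (median centring alone). The list had adjusted p = 0.731 with an estimated correlation. Of 54 members, 31 were higher in both lines, 8 lower in both and 8 at least 2-fold higher in both, and 13 passed limma adjusted over the list alone. Os01g0558100 was 6.95-fold above wild type (2.80 ± 0.67) and Os10g0529500 5.10-fold (2.35 ± 0.08). Genes of jasmonate synthesis and signalling rose with a median of 0.40 (0.62 in line 4 and 0.15 in line 18, camera adjusted p = 0.0381). They had adjusted p = 0.756 with an estimated correlation, and the call also ended in the deposited table (camera adjusted p = 0.0617, the highest of 12 settings). The lowest, 3.8e-04, came from spike-in centring, which tests no list. The lowest of the others was 0.00919, without accidental members. Of 34 members, 19 were higher in both lines and 7 lower in both, and 0 passed limma adjusted over the list alone. Lipoxygenases, enzymes at the entry to jasmonate synthesis, had ratios of 1.81 ± 0.76 (Os08g0509100), 1.72 ± 1.20 (Os12g0559200) and 1.68 ± 1.07 (Os12g0560200).

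Other defence lists did not pass camera in the main setting. Over 12 other settings, NBS-LRR proteins passed in 7, class III peroxidases in 5 and terpene synthases in 2, and phenylpropanoid enzymes and receptor kinases in 0. The 12 include spike-in centring, which tests no list and in which the terpene synthases passed. The NBS-LRR resistance proteins, receptors of the immune system, had a median of 0.14 (0.12 with members at their bounds where wild type or the lines were dim; range 0.06 to 0.19; adjusted p = 0.0553). Of its members, 83 of 167 were higher in both lines and 34 lower. Among them Os11g0226800 was at least 3.01-fold above wild type, Os07g0117000 stood at 1.31 ± 0.11, and Os05g0380300 at -1.48 ± 0.24. The class III peroxidases had a median of -0.09 (range -0.24 to -0.03, adjusted p = 0.0568), with 16 of 74 higher and 29 lower in both lines. By limma 4 passed adjusted over the list alone. Besides the high POC1, they include Os03g0234900 (4.70-fold lower, -2.23 ± 0.22), Os05g0135500 (4.57-fold lower, -2.19 ± 0.54) and Os03g0339300, at least 4.35-fold below wild type since the lines were not well above background. The diterpenoid phytoalexin and terpene synthases, whose products include the antimicrobial compounds of rice, had a median of 0.69 (0.86 in line 4 and 0.14 in line 18, adjusted p = 0.183), with a range of 0.20 (36 genes, no filter) to 0.96. Of these, 9 of 23 passed limma adjusted over the list alone, and 5 were at least 2-fold higher and 3 at least 2-fold lower in both lines. The terpene synthase Os11g0286800, named above, stood at -2.51 ± 0.08. Ratios were 3.56 ± 2.81 for the terpene synthase Os02g0570400 and 3.13 ± 2.01 for the ent-kaurene oxidase Os06g0569500. The terpene synthase Os04g0179700 was measured 6.48-fold above wild type, which was not well above background for it. Phenylpropanoid enzymes had a median of 0.23 (adjusted p = 0.0977, 12 of 69 passed limma adjusted over the list alone). Wall-associated and lectin receptor kinases had 0.11 (adjusted p = 0.417), among them the kinase Os04g0598900 at 1.25 ± 0.59.

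The histones and cell cycle genes, markers of dividing cells, fell with a median log2 ratio of -0.25 (-0.35 in line 4 and -0.15 in line 18, camera adjusted p = 2.0e-06), with a range of -0.36 to -0.10 (median centring alone). This became adjusted p = 0.731 with an estimated correlation. Of 54 members, 36 were lower in both lines and 5 higher in both, and 0 passed limma adjusted over the list alone. A histone H2A gene (Os03g0162200) was 3.47-fold below wild type (-1.80 ± 0.56), a histone H3 gene (Os06g0160100) 2.61-fold (-1.38 ± 0.44) and histone H4 genes 2.51-fold (Os02g0684500, -1.33 ± 0.06) and 2.39-fold (Os04g0583600, -1.26 ± 0.46). The ribosomal proteins, parts of the translation machinery, fell with a median of -0.20 (-0.11 in line 4 and -0.28 in line 18, camera adjusted p = 1.4e-07). With median centring alone the median was -0.00871 and the adjusted p 0.0363. They had adjusted p = 0.731 with an estimated correlation. Of 296 members, 172 were lower in both lines and 20 higher in both, with 1 at least 2-fold lower in both and 0 past limma adjusted over the list alone. The plastid-specific 30S protein 1 (Os03g0856500) was 2.46-fold below wild type (-1.30 ± 0.41). The 50S proteins L18 (Os03g0828100) and L24 (Os06g0683200) had ratios of -1.20 ± 0.57 and -1.17 ± 0.36, and the 40S protein S10-1 (Os01g0962600) had -0.74 ± 0.06.

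The chlorophyll biosynthesis enzymes fell with a median of -0.32 (camera adjusted p = 0.0123). They had adjusted p = 0.731 with an estimated correlation. Here 8 of 14 were lower in both lines and 0 higher in both, with 0 past limma adjusted over the list alone. Line 4 carried most of this, with a median of -0.62 against -0.09 in line 18, where it stood at percentile 13.2 of random lists of similar signal. The call ended with median centring alone (median -0.10, camera adjusted p = 0.147, the highest of 12 settings). The lowest, 0.00509, came from spike-in centring, which tests no list, and the lowest of the others was 0.0107, without accidental members. The magnesium chelatase subunit chlI (Os03g0563300), which inserts magnesium at the entry to the pathway, was 7.32-fold below wild type in line 4 and 1.41-fold in line 18 (-1.69 ± 1.68). The next enzyme, magnesium-protoporphyrin O-methyltransferase (Os06g0132400), had -1.33 ± 0.95. Light harvesting and photosystem proteins had a median of -0.03 (-0.09 in line 4 and 0.05 in line 18, range -0.07 to 0.13, adjusted p = 0.267; 20 of 65 higher and 21 lower in both lines, 3 past limma adjusted over the list alone). The list passed in 1 of 12 other settings, spike-in centring, which tests no list. Without accidental matches 45 of its 65 genes remained, with a median of -0.04 (camera adjusted p = 0.143). A gene described as the photosystem II D1 protein (Os04g0235200) stood at -1.84 ± 0.11. Genes described only as plastocyanin-like domain proteins lay on both sides, Os06g0218600 at -1.80 ± 0.35 and Os09g0572700 at 1.37 ± 0.37. Calvin cycle enzymes had a median of -0.09 (-0.15 in line 4 and 0.06 in line 18, range -0.11 to 0.17, adjusted p = 0.284; 10 of 28 higher and 12 lower in both lines), and a gene described as a Rubisco large chain (Os06g0672400) had -1.64 ± 0.43. Another of that description, Os01g0791600, had 1.65 ± 1.66.

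The transposable elements rose with a median of 0.21 (0.20 in line 4 and 0.15 in line 18, camera adjusted p = 0.045). They had adjusted p = 0.731 with an estimated correlation. Here 52 of 96 were higher in both lines and 14 lower in both, with 0 past limma adjusted over the list alone. The call ended with median centring alone (adjusted p = 0.109), with no filter on dim probes (0.132) and with signals above background required in both channels (0.150). Over 12 settings the adjusted p by camera ranged from 7.9e-05 to 0.150. The lowest came from spike-in centring, which tests no list, and the lowest of the others was 0.0114 with Feature Extraction signals. A GAG-POL gene (Os11g0617500) was 14.1-fold above wild type in line 4 and 1.88-fold in line 18 (2.36 ± 2.06). The En/Spm-like genes Os07g0431000 and Os03g0714800 had 1.52 ± 1.102 and 1.15 ± 0.47, and the IS4 transposase Os08g0459400 had -0.98 ± 0.29. On the same arrays, rice genome control probes read 0.12 above random and artificial control probes in line 4 (two-sided permutation p = 0.00011) and -0.02 in line 18 (two-sided permutation p = 0.410). Both p-values measure the spread among probes of 1 array, not between RNA samples, and the difference between the arrays was not tested.

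The remaining lists did not pass camera in the main setting. Over 12 other settings, including spike-in centring, which tests no list, late embryogenesis abundant proteins passed in 5 and the clock list in 4. The others of this paragraph passed in 0. The late embryogenesis abundant proteins and dehydrins, which accumulate in drying cells, had a median of 0.23 (range 0.15 to 0.40, adjusted p = 0.0729; 15 of 29 higher and 7 lower in both lines). Genes of abscisic stress ripening protein 1 had 2.11 ± 1.32 (Os01g0959200), 1.85 ± 1.31 (Os01g0959100) and 1.60 ± 0.58 (Os02g0543000), and a dehydrin (Os11g0454000) 0.82 ± 0.01. The circadian clock list had a median of -0.20 (-0.40 in line 4 and -0.06 in line 18, range -0.59 in the deposited table to -0.10 with no filter, adjusted p = 0.0611), and of its 19 genes 5 are clock or light-input genes, with a median of -0.45 and adjusted p = 0.0615. Its 4 top members are transporters of cations (Os01g0130000, -0.61 ± 0.04, and Os04g0298200, -0.53 ± 0.22) and of auxin (Os08g0191000, -1.17 ± 0.89, and Os01g0643300, -0.52 ± 0.02). Medians and adjusted p were 0.20 and 0.194 for nitrogen, phosphate and sulfate transport (7 of 53 past limma adjusted over the list alone) and -0.05 and 0.220 for auxin response. They were 0.23 and 0.378 for root and iron supply genes, -0.07 and 0.434 for senescence, and 0.09 and 0.464 for heat shock proteins. They were 0.28 and 0.581 for NAC factors and 0.15 and 0.652 for sucrose, starch and trehalose metabolism (2 of 95 past limma adjusted over the list alone). For antioxidant enzymes they were 0.05 and 0.910, and for seed storage proteins, a marker of seed tissue, 0.12 and 0.980 (4 of 32 past limma adjusted over the list alone). Of those 32 genes 11 remain without accidental matches, with a median of 0.63 (adjusted p = 0.2002). Without such matches the medians also moved to 0.19 for receptor kinases (18 genes), -0.02 for senescence (10 genes) and 0.02 for cytokinin and strigolactone (28 genes). The medians of line 4 and line 18 had opposite signs in 5 lists: light harvesting, Calvin cycle, gibberellin genes (0.00472 and -0.06), cell wall growth enzymes (-0.06 and 0.08) and seed storage proteins (0.17 and -0.000198). In 5 lists the test, the median and the mean differed in sign. For gibberellin genes the test and the mean (-0.25) were negative and the median (0.05) positive (adjusted p = 0.417). The test was negative and median and mean positive for AP2/ERF factors (0.06 and 0.00238, adjusted p = 0.759) and for cell wall growth enzymes (0.07 and 0.03, adjusted p = 0.820). For NF-Y subunits (-0.04 and 0.00889, adjusted p = 0.450) and the cytokinin and strigolactone pathway (-0.02 and 0.01, adjusted p = 0.741), test and median were negative and the mean positive.

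**Figure D3:**
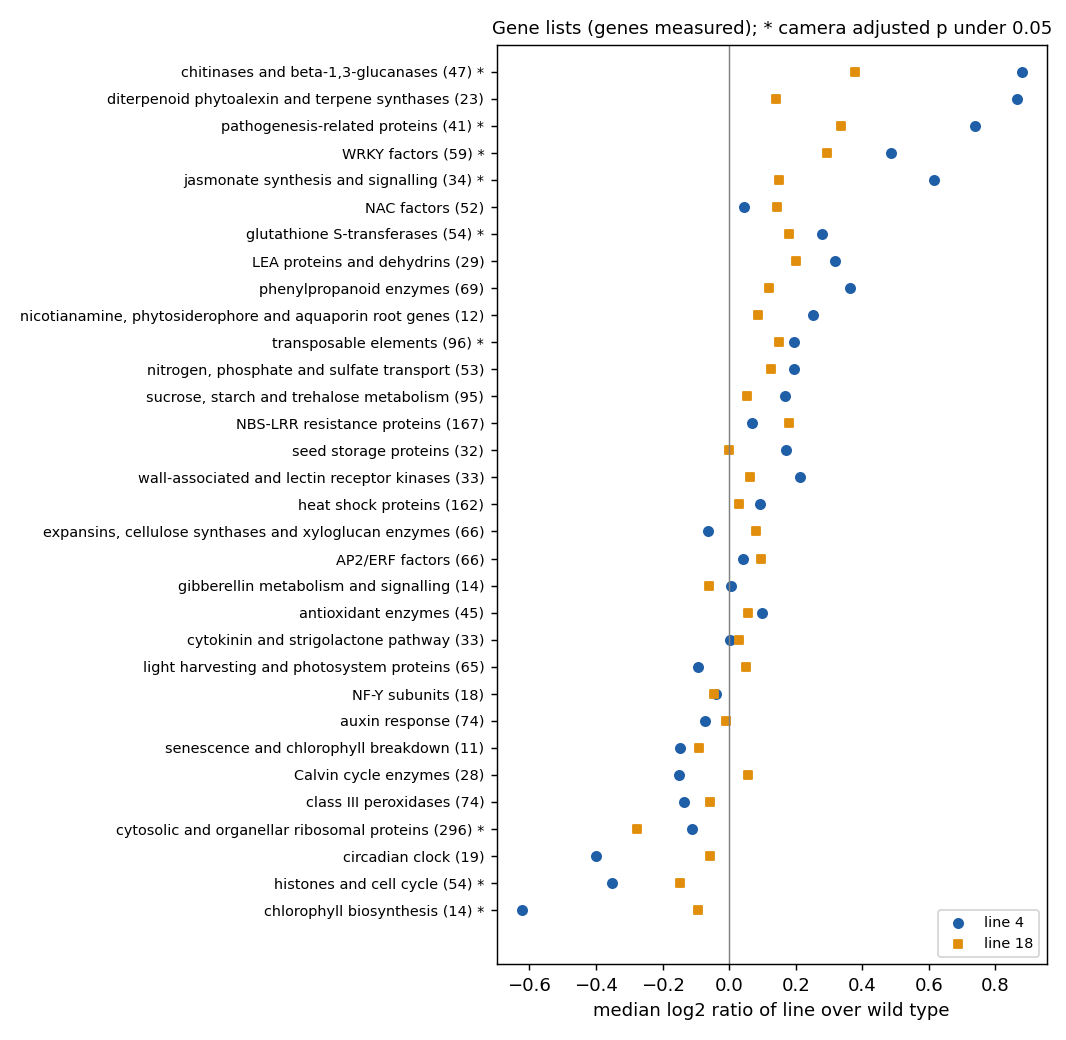
Median log2 ratio of line over wild type (horizontal axis) of the 32 gene lists, with the number of measured genes in brackets. Circles are line 4, squares line 18, and a star marks camera adjusted p under 0.05. The 6 starred lists that rose lie above 0 in both lines and the 3 that fell below 0 in both. With an estimated correlation none of the 9 passed (adjusted p = 0.731 for 8 lists and 0.756 for the jasmonate list).

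The comparison of the lines with each other asks how far the 2 transgenic events share the same ratios. Across genes, the ratios of line 4 and line 18 had a Pearson r of 0.566 and a Spearman rho of 0.601, and 72.0% of genes had the same sign. A simulation with a shared control and no change gave an r of 0.501 (0.486 to 0.522 over 100 draws) and 66.7% of the same sign (65.8 to 67.5). These values follow from giving both lines and the control the same spread, which the 2 lines did not have. Genes are not independent replicates. The ratios were spread wider in line 4 (median absolute deviation 0.56) than in line 18 (0.29). Among the genes that differed most, a terpene synthase (Os12g0491800) read 5.41 in line 4 and 0.30 in line 18, and a ZIM domain gene of the family of jasmonate repressors (Os07g0153000, whose probe sequence another locus shares) 5.35 and 0.59. A lipase/lipoxygenase domain gene (Os10g0361000) read 4.26 and -0.66, and a BURP domain gene (Os10g0409400) 1.14 and -3.44. Wild type was not well above background for Os12g0491800 and Os07g0153000, whose means as measured were 7.24-fold and 7.82-fold above it. Both ratios are against wild type in the same dye, and the labels do not say whether the arrays had the same RNA; their Cy3 signals correlated at 0.9985. The covariance was 0.221, against 0.124 (0.118 to 0.133 over 100 draws) in the simulation with a shared control and no change. How much of the excess comes from the control was not split off, since no second control was labelled. With 1 array per line the difference between the lines has no test.

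The level of OsHAP2E itself was sought among the NF-YA genes, since neither the array descriptions nor the reference table tie a locus to this name. The NF-YA gene Os03g0696300 was 2.30-fold above wild type in line 4 and 6.20-fold in line 18 (1.92 ± 1.01, adjusted p = 0.273 by limma), and a second probe of it read 0.85 and 2.01. No other NF-YA gene was at least 2-fold above wild type in both lines. The count of 1 became 0 with both arrays scaled to the same spread or with line 4 centred on the spike-in spots. Os12g0613000 read -0.78 in line 4 and -0.23 in line 18, and Os03g0411100 -0.58 and -0.12. Os05g0463800, a CCAAT-binding factor whose description does not name its subunit, read -0.98 and -0.10. Means lay between -0.23 and 0.15 for Os03g0647600, Os07g0608200, Os08g0196700 and Os12g0618600, the last dim in wild type. Os07g0158500 was not well above background in either channel. Among the other NF-Y subunits, the HAP3 gene Os08g0174500 had 0.43 ± 0.42, the HAP5 gene Os09g0480700 had -0.40 ± 0.48 and the HAP3 gene Os01g0834400 had 0.12 ± 0.18. The other 7 had means between -0.31 and 0.21. A probe outside the part of the gene carried by the construct would not read the transgene, and the sources used here do not give which part that is.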

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

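The tests of genome control probes, gene models against negative controls, repeated elements, the dye effect and the wild type RNA were chosen, with their limits, only after the result was seen; the others were written before the value they measure was seen.

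Control spots that the comparisons do not use gave a pair of signals. The E1A spike-in spots (10 spikes of 32 spots each), which are no rice sequence, read a mean of 1.95 higher on the log2 scale (SD 0.20 over spikes, 3.86-fold) on the line 4 array than on the line 18 array, in 10 of 10 spikes. This ratio is relative to rice genes: the raw Cy5 signals of the spikes were 1.47 to 1.83 times as high on the line 4 array (median 1.70), while the median rice signal above background in Cy5 was 2.08 times as high on the line 18 array; the labels do not say how much spike-in RNA was added. Rice genome control probes read 0.124 above random and artificial control probes on the line 4 array (bootstrap interval 0.0333 to 0.224, 24 probes against 24, two-sided permutation p = 0.00011 with 100000 permutations) and -0.02 on the line 18 array (p = 0.410 by the same permutation test). The interval and p-values measure the spread among probes of 1 array, not between RNA samples. The difference between the arrays was not tested.

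The second signal goes with a pattern among genes: those read by a probe sequence of 5 to 9 loci had a median of 2.39 in line 4 and 0.23 in line 18, and those of 10 or more loci 2.26 and 0.13, against 0.02 and 0.03 for genes of 1 locus. The 179 genes of 5 to 9 loci are read by 28 sequences and the 409 genes of 10 or more loci by 18, so they are not separate measurements. Genomic DNA in the line 4 sample is a candidate explanation. Gene models of 1 locus with no named transcript that were dim in wild type (870 probes) were compared with negative control spots in Cy5. They stood 1.70 times as far above them on the line 4 array as on the line 18 array (bootstrap interval 1.55 to 1.90, all spots 0.483). The explanation needs this, but the raw Cy5 signals of the E1A spikes, no rice sequence, were also 1.47 to 1.83 times as high (median 1.70). The gene models therefore cannot tell DNA from a gain in Cy5 that the spikes share. The genome control probes differed by 0.124, as the explanation needs. The gene models' ratio of signals over local background, 4.45, decides nothing, since the line 18 signal of 3.16 is smaller than the offset of negative controls (-5.94). Transcripts of repeated elements in line 4 stay open, since transposable element genes of 1 locus read 0.194 above other genes there (bootstrap interval 0.0949 to 0.509), though they also had a median of 0.15 in line 18, against 0.03 for all genes of 1 locus. No test separated DNA, a wider transcription of the genome in line 4 and a gain in Cy5 that the spikes share, so each may contribute. On the log2 scale of the medians of 2.39 and 2.26, the spikes read 1.95 higher in line 4 than in line 18.

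Ratios were spread 1.98 times as wide in line 4 as in line 18. Spot noise falls short: spots of 1 probe had a median SD of 0.0531 on the line 4 array (90th percentile 0.147), where an SD of 0.487 would be needed. Loss of 5' parts of transcripts in the line 4 RNA falls short as the whole cause, since probes that reach into the 3' UTR (15780 genes) kept a ratio of spreads of 1.83 (bootstrap interval 1.79 to 1.87); a part stays open for the 299 genes read in the coding sequence or 5' UTR, with a ratio of 2.42 and a line 4 median of -0.16 against 0.01. The same changes at a larger size in line 4 stay open: 88.9% of genes at least 2-fold from wild type in line 4 had the same sign in line 18 (exact binomial interval 87.8 to 89.9, genes taken as independent). This is under the share set beforehand for this explanation. A simulation of a shared control with no change gave 83.5%, but with the same spread in both lines, which these arrays did not have. That value is therefore only a rough guide. A difference between the transgenic events remains untested, with 1 array per line.

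The pathogenesis-related and chitinase lists stood above wild type on both arrays on a scale centred on all genes, with medians of 0.74 and 0.88 in line 4 and 0.33 and 0.38 in line 18. A dye effect specific to these genes cannot be told apart from the genotype, since the dyes were never exchanged: their members (88 genes) read 0.253 higher in line 4 than in line 18 at the median, with a bootstrap interval of -0.0683 to 0.551 that includes equal ratios. The state of the wild type RNA stays open in the same way, as the Cy3 signals of both arrays correlate at 0.9985 across spots and a deviation of an RNA used on both would enter both ratios. Overexpression of OsHAP2E, the difference that the design names, stays among the open explanations.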

How the results depend on the processing

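The settings with 1 gene per probe sequence, lists without accidental members and spike-in centring were chosen only after the data were seen. No paired analysis was possible because each line has 1 array with wild type on the same array and the labels pair no further samples. None of the 9 called lists turned in direction by camera, while 7 uncalled lists did in 1 or 2 settings, NBS-LRR proteins with median centring among them (adjusted p 0.928). The gene count of 0 by limma stayed 0 in the planned settings that refit limma, with trend, robust and treat as well (3348, 3168 and 901 genes at an unadjusted p under 0.05). It was 8 with spike-in centring, and 3126 genes (1713 higher, 1413 lower, 169 of opposite signs) had a Feature Extraction p under 0.01 on both arrays with 1 sign. The 613 shared 2-fold genes were 1110 with a normexp offset of 0, 1534 with Feature Extraction signals, 1479 in the deposited table, 395 with spike-in centring (shared with the 613: 612, 603, 458 and 301) and 1849 at 1.5-fold; single lines gave 980 to 3449. Scaling to the same spread gave 626, of which 420 were shared. The share of them that is higher, 63.6%, was 78.1% with median centring and 19.8% with spike-in centring, which moved the median of all genes from 0.04 to -0.93. The correlation of 0.566 was 0.591 with Feature Extraction signals, 0.392 with median centring, 0.556 with no filter, 0.575 in the deposited table, 0.599 with 1 gene per sequence and 0.619 in the upper part of the signal range. Called lists numbered 8 to 12 over the settings, 0 with estimated correlation, 0 with fry and 17 outside the central random lists. Of the 9 called, 6 kept an adjusted p under 0.05 in 12 of 12 settings, though their medians moved by over 1.5 times: ribosomal proteins to -0.00871, histones to -0.10 and glutathione S-transferases to 0.38 with median centring, pathogenesis-related proteins to 0.75 with Feature Extraction signals and in the deposited table, and with no filter chitinases to 0.19, pathogenesis-related proteins and WRKY factors to 0.23 and glutathione S-transferases to 0.16. The 12 settings include spike-in centring, which tests no list. They also include the lists without accidental members, which changed none of these 6 lists and so could not end their calls. Spike-in centring did move their adjusted p by camera. It rose to 6.7e-05 for ribosomal proteins and to 3.1e-05 for histones, and fell for the others. Of the 23 others, 6 passed in some: NBS-LRR proteins in 7 (lowest adjusted p 0.0174), peroxidases in 5 (0.00246), late embryogenesis abundant proteins in 5 (0.0174), the clock list in 4 (0.0411), terpene synthases in 2 (2.0e-07, spike-in centring) and light harvesting in 1 (0.0427, spike-in centring). The passes with spike-in centring say nothing about these lists, since it tests none. Chlorophyll biosynthesis ended with median centring (0.147) and ranged from percentile 0.07 to 13.22 in single lines; transposable elements ended with median centring (0.109), no filter (0.132) and both channels above background (0.150); the jasmonate list ended in the deposited table (0.0617). With estimated correlation adjusted p was 0.731 for 8 lists and 0.756 for jasmonate. With fry it was 0.290 for chitinases, WRKY factors and glutathione S-transferases, 0.364 for pathogenesis-related proteins, 0.6004 for chlorophyll, 0.395 for ribosomal proteins, 0.329 for histones, 0.549 for jasmonate and 0.368 for transposable elements. NF-YA genes at least 2-fold above wild type numbered 0 with equal spread and 0 with spike-in centring. Of 107 named genes, 12 changed sign with spike-in centring, which lowers all genes alike and so tests none of them, 5 with median centring, 2 in the deposited table (Os10g0409400 among them), 2 with the mean of probes and 1 each with Feature Extraction signals and equal spread; 14 had no value with both channels above background. The cause of these moves was not tested, except that fewer genes enter the stricter filters. Without a replicate, limma, the correlation and camera give no value, since 1 array leaves no residual degrees of freedom. Over 8 groups of genes by signal, the correlation was lowest, 0.457, in the second dimmest and highest, 0.686, in the brightest; whether signal is the cause was not tested.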

Other observations

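The genes and the split of the ribosomal proteins named here were chosen after their values were seen. The test of neighbouring loci was written before its value was seen.

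Members of some gene families stood on both sides of wild type in both lines. Of the plant metallothioneins of family 15, Os05g0202800 read 4.66 in line 4 and 3.59 in line 18, while Os05g0111300 read -2.11 and -2.05. Of the acid phosphatases of class B, Os05g0190500, Os05g0189900 and Os05g0189300 read -3.89, -2.52 and -1.36 in line 4 and -4.14, -1.36 and -1.24 in line 18, while Os01g0191200 read 0.44 and 0.89. Among the ribosomal proteins, 29 of the 41 described as 30S, 50S or chloroplast proteins were lower in both lines, with medians of -0.38 in line 4 and -0.30 in line 18. Of the 157 described as 40S or 60S proteins 86 were lower in both, with medians of -0.08 and -0.29, and of the 98 others 57, with -0.10 and -0.26.

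Some genes stood apart in 1 line. Cryptochrome 1 genes read -1.04 (Os02g0573200) and -0.93 (Os04g0452100) in line 4 and -0.06 and -0.04 in line 18, and the flowering regulators FKF1 (Os11g0547000) and Gigantea (Os01g0182600) read -0.78 and -0.76 in line 4 and -0.12 and 0.19 in line 18. ZIM domain genes, the family of jasmonate repressors, read 4.11 (Os03g0180900) and 2.93 (Os10g0392400) in line 4 and 0.87 and -0.24 in line 18. A prolyl endopeptidase (Os04g0561500) read 1.31 in line 4 and 4.59 in line 18. The differences between the lines were not tested, with 1 array per line.

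As a hypothesis, genes with at least 2-fold ratios in both lines where wild type or the lines were dim (19 and 11 genes) may lie in segments that differ between the transgenic and the wild type plants. Neighbouring loci with different descriptions formed 1 pair among them (Os10g0360600 and Os10g0360700), where random draws gave 0.0471 on average and reached 1 in their upper tail, which leaves this open. The pair is described only as a hypothetical and a conserved hypothetical protein, so the descriptions cannot tell whether they are copies of 1 family.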
